A study of Triticum aestivum with 12 samples.

How the data were processed

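The data are 12 RNA sequencing libraries from crowns of the wheat cultivar Jing411, in 4 groups of 3 biological replicates: unacclimated (NTG), cold acclimated (LTA), and each of these after freezing (NTGF and LTAF). Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with standard Illumina protocols. The labels' tissue field reads differently from the extraction protocol, and the crown is taken from the latter. The authors deposited a table of raw read counts per gene model, with a column for each library, per the file headers. It holds whole numbers with no normalization, for 128497 gene models, of which 82323 are high-confidence (HC) and 46174 low-confidence (LC) by their identifiers, and 0 of them are at 0 in all libraries. The aligner, the counting program, the genome build and the annotation are not given in the sources used here, nor is the treatment of reads that match several copies of a gene. Wheat carries 3 subgenomes with near-identical gene copies, so such reads could be divided, doubled or dropped between copies.

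Total counts per library ran from 17871036 to 21491305. Reads without molecular identifiers are not independent molecules, so the counting intervals and floors given here cover counting error only. A gene without a count in a group is given as a bound against a floor of 3 counts over that group's 3 libraries. A gene with 1 to 3 counts is given as a ratio with its 95% exact counting interval.

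Groups were taken from the labels, and every column was matched to a library by its name. Counts were scaled with TMM and filtered with filterByExpr (minimum count 10), which left 69693 models (57596 HC and 12097 LC) that hold at least 99.38% of the counts of each library. All 12 libraries entered a single fit with a mean per group in edgeR 4.0.16 (R 4.3.3), with the quasi-likelihood F test, robust estimation and Benjamini-Hochberg adjustment, and genes under an adjusted p of 0.05 were called. The 5 comparisons were LTA against NTG, NTGF against NTG, LTAF against LTA, LTAF against NTGF and the interaction, which is the freezing response of acclimated plants minus that of unacclimated plants on the log2 scale. The common biological coefficient of variation was 0.273. Levels are given as CPM, counts scaled to the TMM-adjusted library size, and log2 CPM uses a prior count of 2. Single values per library were compared with exact two-sided permutation tests.

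The rule for named genes took, per comparison and direction, the 8 called genes with the largest fitted fold change that had a mean of at least 10 CPM in the higher group and, except for the interaction, no overlap between the groups compared. Its condition on gene descriptions could not be applied, since the table holds no descriptions. Because the identifiers carry no names, the first 2 in each direction are printed. The reference table of wheat gene names matched 0 identifiers, so 0 of the 44 gene lists written before the data were examined had a member, and no gene list was tested. Chromosome, subgenome, confidence class and order along the chromosome were read from the format of the identifiers, and groups made from them were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation. These groups were chosen after the table was seen.

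Runs of neighbouring genes were sought among tested HC models placed on 21 chromosomes. Log2 fold changes, limited to 3 in either direction, were averaged over windows of 15 genes, and the highest window mean in each of 1000 shuffles of gene order gave the threshold. Overlapping windows past it were joined, and a run had to hold at least 5 called genes. The limit and this minimum were set after an earlier version gave runs that rested on single genes, and the scan as a whole was chosen after the data were examined. Shuffling treats genes as exchangeable, so its p describes gene order in these libraries and does not replace replicates. The mean fold changes given for runs are not limited.

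The slope of one response on another was fitted by least squares on mean log2 CPM over the genes called in the response on the horizontal axis. Selection of called genes and measurement error lower such a slope, so equal responses were simulated in 4 draws each, and their slopes stand beside the measured ones. These simulations gave each gene a single spread in all libraries, so they do not hold the unequal spread of the groups.

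The steps were tested on simulated counts with the real library sizes. Each gene had its real mean, averaged over the groups compared, and a single spread shared by all libraries. The unequal spread of the groups is therefore left out. In the simulations of calls 200 genes were changed. In the simulation of LTA against NTG (66394 genes), edgeR recovered 9% of genes changed 2-fold and 60% of those changed 4-fold. For LTAF against LTA (63996 genes) it recovered 2% and 55%, and for the interaction (66692 genes) 0% and 34%. DESeq2 recovered 34% and 75%, 23% and 69%, and 9% and 54% in the same 3 simulations, but between 35.5% and 38.8% of its calls were false, against at most 5.48% for edgeR. With so few changed genes the cut on the unadjusted p is stricter than in the data. The shares of recovered and of false calls therefore hold for these simulations only. The scan for runs found 3 of 3 planted runs of 20 genes changed 8-fold and 0 others among 54864 genes for LTA against NTG.

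The alternatives set before the data were examined were DESeq2 size factors in edgeR, no filter, a filter of 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom, a 2-fold threshold, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library in turn. Scaling by library totals, HC models only, and windows of 10 and 25 genes were added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library or column was left out.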

Results

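The transcriptome of wheat was measured by RNA sequencing in 12 libraries of the cultivar Jing411. RNA came from crowns, the short stem base from which new leaves and roots grow, per the labels' extraction protocol. The libraries fall into 4 groups of 3 biological replicates. NTG plants were kept at 20 °C for 28 days, and LTA plants were cold acclimated at 4 °C for 28 days. NTGF and LTAF plants had the same treatments and were then frozen at -5 °C for 24 hours. Each library held between 17871036 and 21491305 counted reads, and between 91530 and 99662 gene models had at least 1 count. The table pairs its gene identifiers with no names or functions, so genes are given by identifier, and gene groups by the chromosome, the order and the confidence class that the identifiers carry. Identifiers ending in LC are low-confidence gene models, and the others are high-confidence models.

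The first principal component, with 46.6% of the variance, put the 6 acclimated libraries at positive values, from 98.7 to 213.1, and the 6 unacclimated libraries at negative values, from -177.3 to -79.4. The second, with 21.2%, put the 6 frozen libraries between 47.2 and 171.7 and the 6 unfrozen libraries between -115.1 and -75.4. On the third, with 12.7%, LTAF replicate 2 lay at 40.1, while LTAF replicates 1 and 3 lay at -96.9 and -116.3. NTGF replicate 1 lay at 113.1 there, and NTGF replicates 2 and 3 at 12.2 and -5.51. Across genes, the rank correlation of LTAF replicates 1 and 3 was 0.978, while LTAF replicate 2 reached 0.936 and 0.917 with them. The NTGF replicates reached 0.932 to 0.947 with each other, the lowest of these between the 2 values of LTAF replicate 2. The NTG and LTA replicates reached 0.964 to 0.979. Genes are not independent replicates, so these values describe the libraries only.

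**Figure D1:**
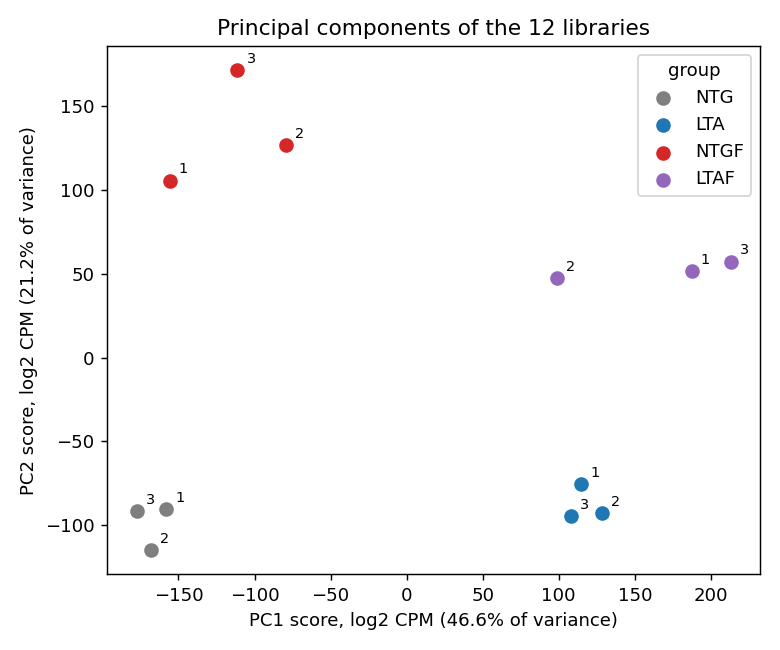
Scores of the 12 libraries on the first 2 principal components of log2 CPM over the 69693 tested gene models, with 1 point per library coloured by group. Acclimated libraries lie at positive values on the horizontal axis (46.6% of the variance) and frozen libraries at positive values on the vertical axis (21.2%).

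LTA against NTG asks what 28 days of cold acclimation change in the crown. Transcripts shifted broadly. The genes that rose in LTA held 25.8% ± 0.453 of all counts in NTG and 53.0% ± 0.499 in LTA, and the genes that fell held 22.8% ± 0.466 and 7.64% ± 0.0703 (SD, n = 3 each). Fewer genes made up 50% of the counts in LTA (2497 ± 79.7) than in NTG (3896 ± 211; SD, n = 3). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. TraesCS2B01G031100 had no count in NTG and 10.2 ± 3.91 CPM (counts scaled to library size) in LTA, at least 249.8-fold higher with a floor of 3 counts over the group (edgeR adjusted p = 2.66e-05). TraesCS5D01G265700 had 1 count over the 3 NTG libraries and 18.6 ± 10.4 CPM in LTA, a ratio of 1450 with a 95% counting interval of 248.1 to 54758 (edgeR adjusted p = 0.000129). Without NTG replicate 1 no count is left and the ratio becomes a bound of 292.6. In the other direction, TraesCS5D01G395600 lay at 12.7 ± 2.82 CPM in NTG and had 1 count in LTA, a ratio of 763.6 (129.1 to 28514; edgeR adjusted p = 7.76e-06), or a bound of 157.8 without LTA replicate 2, which holds that count. TraesCS6B01G361400 lay at 17.2 ± 11.02 CPM in NTG and had 3 counts in LTA, a ratio of 338.9 (114.2 to 1624; edgeR adjusted p = 7.03e-05), which is 214.6 without NTG replicate 1 and 655.8 without LTA replicate 2.

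Some of this change lay in runs of neighbouring genes. A run here is a stretch of tested high-confidence models, in identifier order, with a mean log2 fold change farther from 0 than chance order gave and at least 5 of its genes called. With windows of 15 genes, LTA held 6 higher and 6 lower runs against NTG, and 7 of these 12 lay on chromosomes 5A, 5B and 5D, which carry 16.5% of the tested high-confidence models. Windows of 10 genes gave 11 higher and 5 lower runs, 9 of the 16 on these chromosomes. Windows of 25 gave 3 higher and 7 lower, with 5 of the 10 there. Near-identical gene copies on 5A, 5B and 5D can share reads, so runs on them need not be independent of one another. Whether they outnumber the share of models was not tested. Group 5 chromosomes of wheat are known to carry loci for frost tolerance and for the response to vernalization, but the identifiers were not matched to these loci. On 2B (models 481000 to 483900), 10 of 20 genes were called higher and 1 lower, and the run's mean rose from -0.00 ± 0.03 log2 CPM in NTG to 2.25 ± 0.38 in LTA (SD, n = 3). A run on 2D (454000 to 455600) went from 0.83 ± 0.14 to 2.63 ± 0.05. Runs on 5A (217200 to 220100) and 5D (225300 to 228400) rose by means of 2.95 and 3.17 on the log2 scale, the 5A run not being found with windows of 25. Runs on 7B (443500 to 446700) and 7D (515400 to 517500) fell by 1.68 and 2.10.

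In all, edgeR's quasi-likelihood test called 13907 genes higher and 12600 lower in LTA than in NTG at an adjusted p under 0.05, out of 69693 tested. Of these, 9212 and 8827 changed at least 2-fold. No chromosome and no subgenome was called against the rest in this or the other 4 comparisons: camera called 0 of 22 chromosome sets and 0 of 3 subgenomes in each, and 0 of either had an unadjusted p under 0.05, with the preset or an estimated correlation. With scaling by library totals in place of TMM, the median of all tested genes dropped by 0.34 on the log2 scale and 29.1% of the called genes were higher, against 52.5%, so direction holds relative to the bulk of genes. That scaling called 9172 higher and 22347 lower genes.

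NTGF against NTG asks what freezing changes in plants that were not acclimated. TraesCS5B01G312300 had no count in NTG and 69.5 ± 13.99 CPM in NTGF, at least 1700-fold higher (edgeR adjusted p = 2.07e-07). Its neighbour TraesCS5B01G312200 rose from 0.121 ± 0.0301 to 515.2 ± 86.7 CPM (SD, n = 3), a ratio of 4262 (2201 to 9138; edgeR adjusted p = 4.88e-08). Both lie in a run of genes on 5B (310800 to 313500) whose mean went from -0.50 ± 0.14 log2 CPM in NTG to 3.16 ± 0.37 in NTGF, with 11 of 15 genes called higher and 2 lower. A run at overlapping numbers rose on 5A (310000 to 312500, from 0.91 ± 0.45 to 3.72 ± 0.39), and a run at higher numbers on 5D (317000 to 319300, from 0.36 ± 0.33 to 4.07 ± 0.28). Chromosomes 5A, 5B and 5D are the homoeologous chromosomes of the 3 subgenomes, whose near-identical copies can share reads.

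Farther along the same chromosomes, runs went down on freezing. On 5A (342000 to 346600), 21 of 26 genes were called lower and the mean went from 0.79 ± 0.15 log2 CPM in NTG to -1.35 ± 0.23 in NTGF. On 5B (341400 to 347400) it went from 1.02 ± 0.23 to -0.99 ± 0.30 with 20 of 26 genes called, and on 5D (347100 to 353000) from 1.11 ± 0.14 to -1.07 ± 0.24 with 21 of 25. Other runs rose on 5A (475600 to 479000), 5B (488900 to 491900) and 5D (490000 to 492500), with mean log2 fold changes of 2.49, 2.09 and 3.05. In total NTGF held 11 higher and 8 lower runs against NTG, 12 of them on group 5 chromosomes, where runs need not be independent of one another. For the 9 runs named here the chance of a run this strong anywhere in the genome under shuffled gene order was 0.001, the smallest that 1000 shuffles can give, for a scan chosen after the data were examined.

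**Figure D2:**
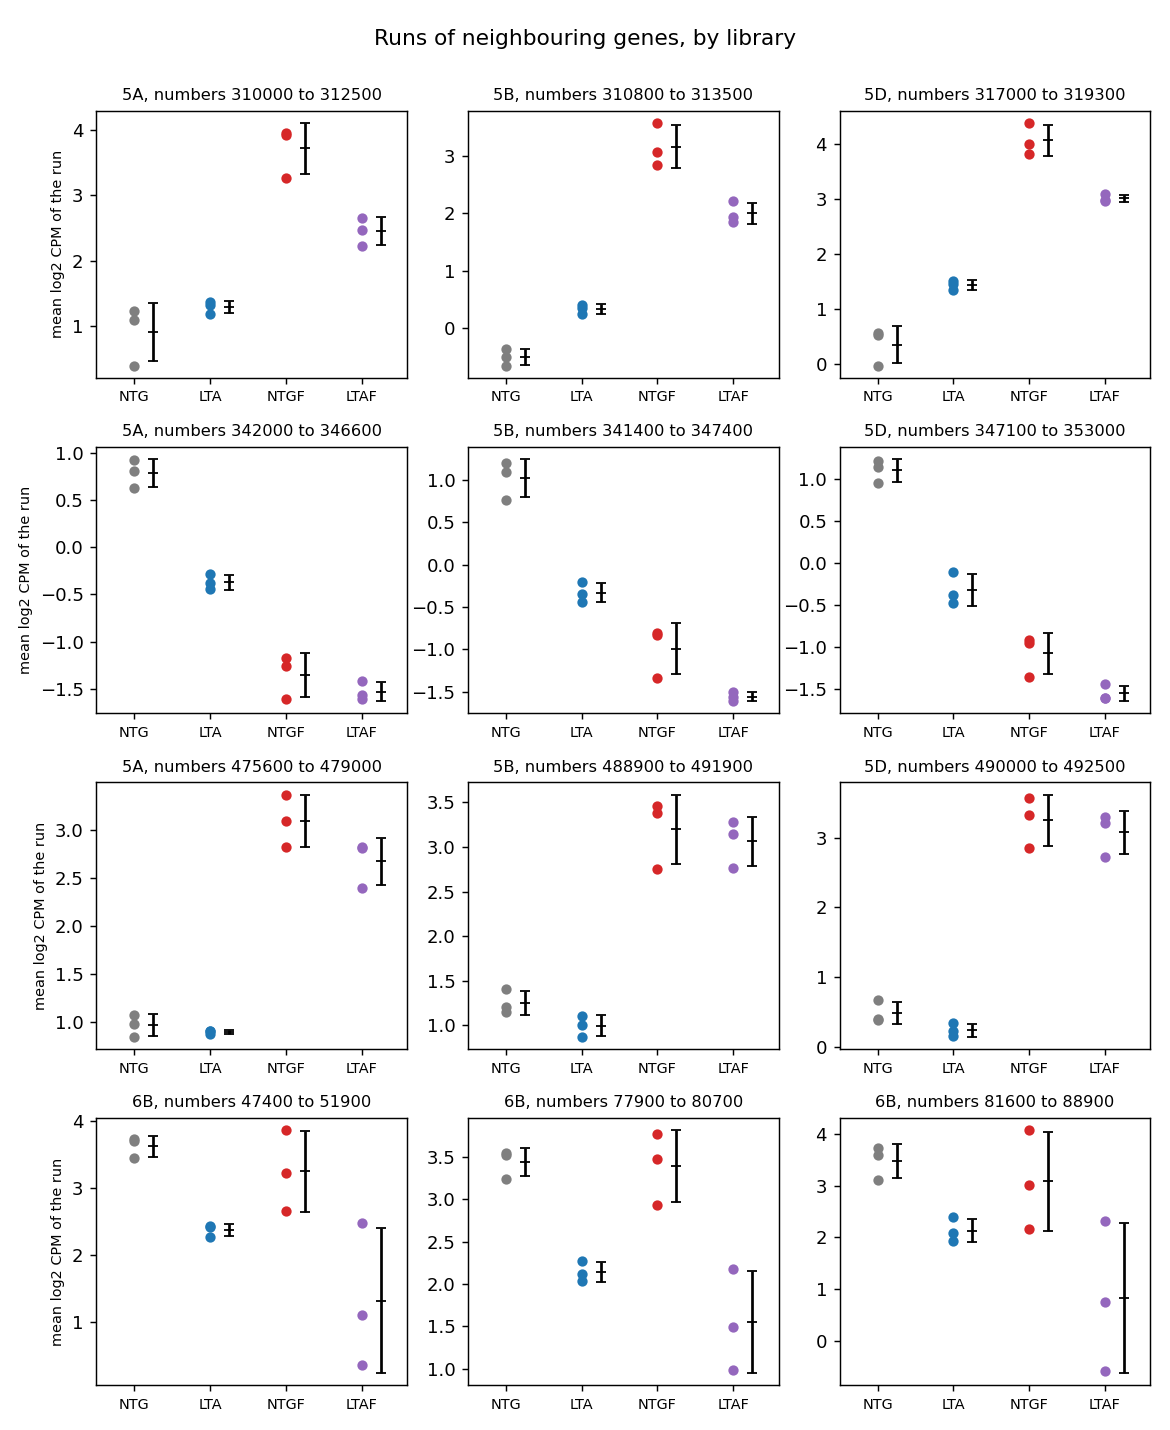
Mean log2 CPM of runs of neighbouring genes on 5A, 5B, 5D and 6B in each library, with 1 point per library and, beside the points, the mean ± SD of each group (n = 3). In the first 3 rows the runs on 5A, 5B and 5D rise or fall together in NTGF, and in the last row LTAF libraries spread widely on 6B (SD 1.08, 0.60 and 1.45).

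In the lowest-numbered part of chromosome 1A, 16 high-confidence models held 117 ± 8.50 counts per library in NTG, 110 ± 12.2 in LTA and 126 ± 26.2 in LTAF, but 18, 3 and 4 counts in the NTGF libraries. The next 13 high-confidence models held 2935 ± 338 counts in NTG and 2520 ± 394 in NTGF (SD, n = 3). The boundary and both sets were chosen after their values were seen.

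**Figure D3:**
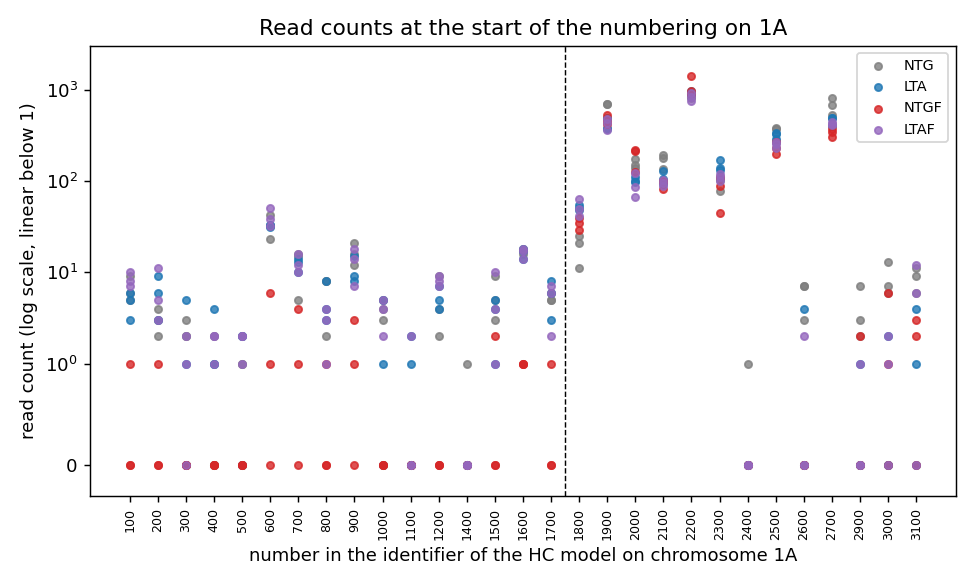
Read counts (vertical axis, log scale, linear below 1) of the lowest-numbered high-confidence models of chromosome 1A, by the number in the identifier (horizontal axis), with 1 point per library coloured by group and a dashed line between the 16 models of the end and the next 13. Left of the line the NTGF libraries hold 18, 3 and 4 counts in all, and right of it 2520 ± 394.

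Among genes with a mean of at least 10 CPM in NTG, the first 2 to fall by edgeR's fitted fold change were TraesCSU01G607400LC, from 14.7 ± 0.850 CPM to no count in any NTGF library (at least 274.6-fold lower), and TraesCS5D01G547500LC, from 10.2 ± 1.75 CPM to no count (at least 190-fold lower). The edgeR adjusted p values were 4.14e-07 and 1.05e-06. Both genes were present in NTG, LTA and LTAF. For genes missing in NTGF only, NTGF plants of another cultivar could not be told apart from a response to freezing. Bounds do not rank genes, and TraesCS3A01G124700LC, with 1 count in NTGF, had a ratio of 1428 (247.3 to 54513), or a bound of 296.3 without NTGF replicate 1, which holds that count. Low-confidence models lay below high-confidence ones, with median log2 fold changes of -0.23 and 0.07 (camera adjusted p = 0.000392, and adjusted p = 0.0203 with an estimated correlation). Without the filter on low counts the gap between these medians was -0.04. edgeR called 9879 genes higher and 8123 lower in NTGF, of which 4862 and 6019 changed at least 2-fold. Genes that rose held 21.9% ± 0.922 of counts in NTG and 36.5% ± 1.93 in NTGF (SD, n = 3), and genes that fell held 10.4% ± 0.756 and 3.22% ± 0.179. A fit of only NTG and NTGF called 5771 higher genes. Scaling by library totals gave 4589 higher and 14594 lower, so that 23.9% of calls were higher against 54.9%, with the median dropped by 0.31 on the log2 scale. Without NTG replicate 1 the counts were 6169 and 5181, and without NTG replicate 2 the count of higher genes was 5436.

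LTAF against LTA asks what the same freezing changes after acclimation. Acclimated plants came to -5 °C from 4 °C and unacclimated plants from 20 °C, so the drop in temperature differs too. TraesCS7B01G332700LC had no count in LTA and 15.4 ± 6.77 CPM in LTAF, at least 294.8-fold higher (edgeR adjusted p = 0.00156). TraesCS5A01G339000 had 1 count in LTA and 35.3 ± 4.92 CPM in LTAF, a ratio of 2118 (360.6 to 79508; edgeR adjusted p = 4.78e-05). Without LTA replicate 1 or 3 the ratio was 1412, and without LTA replicate 2, which holds the count, the bound was 437.8. TraesCS6B01G122700 fell from 14.1 ± 0.367 to 0.864 ± 0.784 CPM, a ratio of 16.4 (12.4 to 23.4; edgeR adjusted p = 0.00397), or 30.99 without LTAF replicate 3. TraesCS7B01G264800 fell from 32.1 ± 1.70 to 2.37 ± 0.773 CPM, a ratio of 13.6 (11.2 to 16.3; edgeR adjusted p = 7.09e-05). Of the 4 runs on group 5 chromosomes that were lower in NTGF, the 3 named above were lower in LTAF against LTA too, and that on 5B (462100 to 463400) was not, at 3.01 log2 CPM in both. On 5A (344700 to 346300) the mean log2 fold change of LTA against NTG was -1.36, and the level went from -0.65 ± 0.14 log2 CPM in LTA to -2.81 ± 0.32 in LTAF. The runs that rose farther along these chromosomes in NTGF rose in LTAF too, on 5A (477400 to 478500) from -1.40 ± 0.12 to 3.36 ± 0.54 and on 5D (491000 to 491700) from -2.47 ± 0.18 to 3.26 ± 0.63. Runs on 7A (198300 to 203900) and 7D (204200 to 207000) rose in LTAF against LTA, with mean log2 fold changes of 2.02 and 2.58, the 7D run not being found with windows of 10. LTA lay below NTG there by means of 1.26 and 1.57, but LTA against NTG gave no run at these genes. Of 26 and 15 genes, 9 and 3 were called lower in LTA, and 1 in each was called higher. Whether part of the rise is a return was not tested. NTGF differed from NTG by means of -0.20 and -0.12 there. The mean interaction terms were 2.22 and 2.70, but the interaction gave no run at these genes, with 3 and 1 called positive and 0 and 1 negative.

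The genes called on freezing after acclimation held a smaller share of the counts than those called without acclimation. Such shares depend on how many genes are called, and they were not computed again with a library left out. Genes that rose held 2.26% ± 0.116 of counts in LTA and 7.03% ± 0.605 in LTAF, and genes that fell held 1.36% ± 0.0871 and 0.580% ± 0.0705 (SD, n = 3). edgeR called 2783 genes higher and 1338 lower, of which 2318 and 946 changed at least 2-fold. DESeq2 called 4287 and 2218, and edgeR with the replicate number as a block called 684 lower. Of the calls 67.5% were higher, and 55.8% with scaling by library totals. Low-confidence models again lay below high-confidence ones (medians -0.26 and 0.00; camera adjusted p = 4.6e-05, and adjusted p = 0.0106 with an estimated correlation), and the gap was 0 without the filter. The counts lean on LTAF replicate 2: without it they were 4405 and 3873, while leaving out LTA replicate 1, 2 or 3 or LTAF replicate 1 or 3 gave 997 to 1396 higher and 356 to 588 lower.

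**Figure D4:**
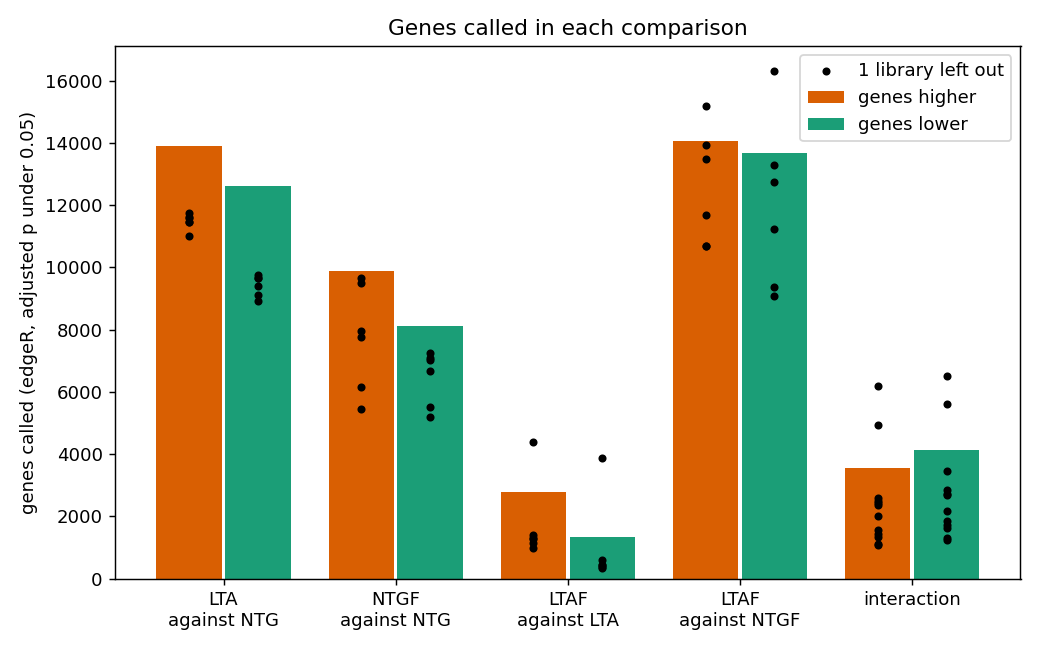
Number of genes called higher and lower by edgeR at an adjusted p under 0.05 in each comparison, out of 69693 tested, with points for the counts when 1 library is left out. Freezing called 9879 and 8123 genes in unacclimated plants, and 2783 and 1338 in acclimated plants.

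The freezing responses of unacclimated and acclimated plants share no library, so no shared control links them, but they start from 20 and 4 °C. Genes that rose in both numbered 1403, where independent lists would share 394.5, and genes that fell in both numbered 392, where 155.9 would be shared. Opposite calls numbered 117 and 73. Over the 18002 genes called in NTGF against NTG, the response of acclimated plants had a slope of 0.311 ± 0.0346 on that of unacclimated plants (SD over the 3 LTAF libraries), where simulated equal responses gave 0.758 to 0.762. Across all tested genes the Pearson correlation of the fold changes was 0.359 and Spearman's was 0.162, over genes that are not independent replicates. The count of shared rises was 677 to 833 without LTA replicate 1, 2 or 3 or LTAF replicate 1 or 3. The count of shared falls was 133 to 244 without any of these or without NTG replicate 2 or 3, and 685 without LTAF replicate 2. It was 611 with DESeq2, 756 with library totals, 258 with a 2-fold threshold, 246 with high-confidence models only and 210 with the replicate number as a block.

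**Figure D5:**
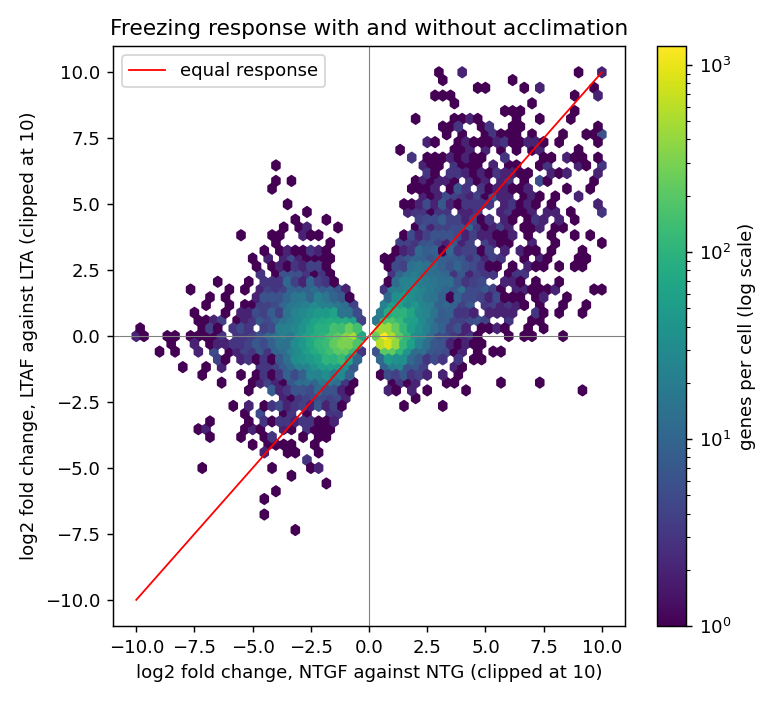
Log2 fold change on freezing in acclimated plants (vertical axis, LTAF against LTA) against that in unacclimated plants (horizontal axis, NTGF against NTG), over the genes called in NTGF against NTG. Each cell is coloured by its number of genes (log scale), values are clipped at 10, and the red line marks equal fold changes. The measured slope of 0.311 was fitted on mean log2 CPM and not on the values drawn. Simulated equal responses gave slopes of 0.758 to 0.762 in such a fit, below the red line.

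LTAF against NTGF asks how frozen plants differ by acclimation, which again cannot be told apart from a difference in growth or stage. TraesCS5D01G547500LC and TraesCSU01G607400LC, without a count in NTGF, lay at 22.01 ± 3.67 and 17.9 ± 3.39 CPM in LTAF, at least 411.6-fold and at least 334.6-fold higher (edgeR adjusted p = 5.2e-07 for both). The limit given above for genes missing in NTGF only holds for both. TraesCSU01G361500LC lay at 16.9 ± 0.232 CPM in NTGF and had 1 count in LTAF, a ratio of 887.5 (154.6 to 34137; edgeR adjusted p = 2.78e-06), or a bound of 189.1 without LTAF replicate 1, which holds that count. TraesCS1D01G412300 had no count in LTAF and 20.6 ± 32.4 CPM in NTGF, at least 351.1-fold lower in LTAF (edgeR adjusted p = 0.015). That size rests on NTGF replicate 1: without it the bound was 33, and the log2 fold change -8.26 against -11.68. The call ended without the filter (adjusted p = 0.0741) and with limma-voom (adjusted p = 0.254), the adjusted p ranging from 1.82e-05 to 0.254 over the alternatives. Runs on 6B (47400 to 51900, 77900 to 80700 and 81600 to 88900) were lower in LTAF, with mean log2 fold changes of -1.65, -1.83 and -1.94. Without LTAF replicate 2 these were -2.73, -2.39 and -3.30, and without NTGF replicate 1 they were -1.22, -1.54 and -1.21. The LTAF libraries spread widely there, at 1.32 ± 1.08, 1.55 ± 0.60 and 0.83 ± 1.45 log2 CPM (SD, n = 3). The run on 2B (482000 to 483900) was higher, at 3.39 ± 0.37 log2 CPM in LTAF and 0.30 ± 0.48 in NTGF, but was not found with windows of 25. Of the runs in LTAF against NTGF, 5 of 13 lay on group 5 chromosomes, but 1 of 14 with windows of 10 and 2 of 8 with 25. With windows of 15, 10 and 25, the interaction had 2 of 4, 0 of 2 and 1 of 3 there. LTAF against LTA had 7 of 15, 8 of 16 and 7 of 14.

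edgeR called 14057 genes higher and 13664 lower in LTAF than in NTGF, of which 9055 and 8985 changed at least 2-fold. A fit of only these 2 groups called 8078 and 7941. Genes higher in LTAF held 19.04% ± 2.13 of counts in NTGF and 43.7% ± 4.94 in LTAF, and genes lower held 33.8% ± 1.53 and 13.9% ± 2.95 (SD, n = 3). Of the genes called in LTA against NTG, 7997 were again higher and 6227 again lower, where independent lists would share 2805 and 2470. The difference between acclimated and unacclimated plants after freezing had a slope of 0.598 ± 0.0448 on that before freezing (SD over the 3 LTAF libraries), where simulated equal differences gave 0.814 to 0.820. Without LTAF replicate 1 the count of lower genes was 9093.

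LTA and NTGF plants, cold in different ways, were each compared with the same NTG libraries. Genes higher in both numbered 4665 and genes lower in both 3001, where independent lists would share 1971 and 1469. The correlation of the fold changes was 0.363 and their covariance 0.623. Simulated unchanged groups against the same NTG libraries gave 0.485 and 0.0781, with 0 shared calls by edgeR. Part of the overlap may come from the shared controls, which 3 libraries are too few to divide.

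The interaction asks whether freezing acts differently after acclimation. Since acclimated plants were already cold, it cannot tell acclimation apart from their smaller drop in temperature, or from a difference in growth or stage. It is negative where the fold change on freezing was lower in acclimated plants. TraesCSU01G607400LC and TraesCS5D01G547500LC, without a count in NTGF, lay at 17.9 ± 3.39 and 22.01 ± 3.67 CPM in LTAF against 16.3 ± 2.45 and 19.4 ± 1.90 in LTA (SD, n = 3; edgeR adjusted p of the interaction = 5.13e-06 and 9.95e-06). In NTG they lay at 14.7 ± 0.850 and 10.2 ± 1.75 CPM, so NTGF alone lacks them. Plants of another cultivar in NTGF cannot be told apart from a response to freezing for such genes. TraesCS5B01G311900 went from 1 count in NTG to 11.5 ± 4.44 CPM in NTGF, and from 5.13 ± 0.628 CPM in LTA to 8.48 ± 2.90 in LTAF (edgeR adjusted p = 0.000199). Its interaction term was -8.45, and -10.10 without NTG replicate 3. TraesCS6B01G288500 went from 2 counts in NTG to 37.6 ± 36.7 CPM in NTGF, and from 5.74 ± 1.82 in LTA to 17.1 ± 0.555 in LTAF. Its edgeR adjusted p was 0.00703, limma-voom gave 0.0869, and the alternatives ranged from 1.73e-08 to 0.0869. Its term of -8.56 became -10.92 without NTG replicate 2 and -7.42 without NTGF replicate 3. The runs on 5A (310500 to 311700) and 5D (317100 to 318500) had mean interaction terms of -2.60 and -3.53. These runs depend on the window: with 10 genes no negative run was found, and with 25 only that on 5D. On 5D the mean was 0.10 ± 0.23 log2 CPM in NTG, 2.07 ± 0.16 in LTA, 3.76 ± 0.23 in NTGF and 2.76 ± 0.17 in LTAF. A run on 6A (93700 to 95400) was low in NTGF, at -0.08 ± 0.44, against 2.09 ± 0.19 in NTG, 3.47 ± 0.04 in LTA and 3.18 ± 0.31 in LTAF, and was not found with windows of 25. A run on 2B (42500 to 45800) was found with windows of 10 and of 25 too. Its mean interaction term was 2.23, with 7 of 20 genes called positive and 0 negative. The levels there were 1.01 ± 0.37 log2 CPM in NTG, -0.34 ± 0.18 in LTA, 0.14 ± 0.61 in NTGF and 0.73 ± 0.17 in LTAF.

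edgeR called 3566 genes with a positive and 4122 with a negative interaction term, and 1454 and 1699 with the replicate number as a block. Of the negative ones, 2283 were higher in both NTGF and LTA than in NTG without a call in LTAF against LTA. Of the positive ones, 1239 were lower in both NTGF and LTA than in NTG, again without a call in LTAF against LTA. The comparisons share libraries with the term, so part of these counts is built in. Scaling by library totals gave 5621 positive and 2169 negative terms, 72.2% positive against 46.4%, with the median raised by 0.23. Without LTAF replicate 2 the counts were 6194 and 6507. Without NTG replicate 1 or 2, LTA replicate 1, 2 or 3, or LTAF replicate 1 or 3 they were 1094 to 2368 and 1252 to 2728, and without NTGF replicate 2 the count of negative terms was 2682.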

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

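The interaction test and the tests on other splits of the libraries were chosen before the data were examined. The response to freezing differed between acclimated and unacclimated plants by a test of the difference itself: edgeR called 3566 genes with a positive and 4122 with a negative interaction term. When the freezing labels were exchanged within each acclimation state, in 100 of the 200 possible splits with the real one included, 1 split, the real one, gave as many genes as the 7688 observed. The highest of the other splits gave 5399. Such an exchange also moves the freezing effect itself. In a state with mixed labels the effect goes into the spread. Where the labels of the other state stay whole, as in the split with 5399 genes, that state's effect goes into the interaction term. The exchanged splits are therefore no test of a difference between the responses, and they neither exclude nor show that chance could give one.

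The genes named for the interaction were picked out by the same test. TraesCSU01G607400LC had an edgeR adjusted p of 5.13e-06 and TraesCS5D01G547500LC of 9.95e-06, both without a count in the 3 NTGF libraries. Both were present in NTG, LTA and LTAF, so another cultivar in NTGF cannot be told apart from a response to freezing. TraesCS6B01G288500 had an edgeR adjusted p of 0.00703, which limma-voom raised to 0.0869 (range over the alternatives 1.73e-08 to 0.0869). TraesCS5B01G311900 had an edgeR adjusted p of 0.000199.

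For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split called 26507 genes for LTA against NTG, 18002 for NTGF against NTG and 4121 for LTAF against LTA, and the highest other split called 0 genes with edgeR in each. For LTAF against NTGF the real split called 27721 and the highest other 1647. In each comparison 1 of the 10 splits, the real one, gave as many genes.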

How the results depend on the processing

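Scaling by library totals, HC models only, the windows of 10 and 25 genes and the overlap under settings not planned for it were chosen after the data were examined. Across all settings, 145 of the counts of called or shared genes lay within 1.5 times the count reported and 69 did not. The named genes kept direction and call in 306 values and lost the call in 3, without a change of sign. The adjusted p of TraesCS1D01G412300 in LTAF against NTGF ended at 0.0741 without the filter and 0.254 with limma-voom, and that of TraesCS6B01G288500 in the interaction at 0.0869 with limma-voom. Run means stayed within 1 standard error, taken over the genes of the run, in 910 values and moved further in 55, none with a change of sign. The falling runs of NTGF against NTG on 5A (342000 to 346600), 5B (341400 to 347400) and 5D (347100 to 353000) reached -1.31, -1.25 and -1.40 at the weakest. In each, 1 of 15 alternatives moved the mean further than that error. Leaving out a library gave -2.61, -2.34 and -2.44 at the weakest.

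With a 2-fold threshold, fewer genes pass by construction: 9212 higher in LTA against NTG, 4862 higher in NTGF against NTG, 9055 and 8985 in LTAF against NTGF, and 258 shared falls on freezing. Scaling by library totals gave 9172 higher and 22347 lower genes in LTA against NTG, 4589 and 14594 in NTGF against NTG, 5621 and 2169 interaction terms, and 756 shared falls. NTG libraries have the highest TMM factors (1.18 to 1.23), so leaving TMM out moves comparisons with NTG. DESeq2 gave 4287 higher and 2218 lower genes in LTAF against LTA and 611 shared falls. Fits of only the 2 groups compared gave 5771 higher and 6582 lower genes in NTGF against NTG and 8078 and 7941 in LTAF against NTGF, but 17236 and 16850 in LTA against NTG and 3807 and 1359 in LTAF against LTA. HC models only left 246 shared falls, with fewer genes tested. For these fits, DESeq2, limma-voom and the missing filter the cause was not tested. The spread between replicates was unequal. The chi-square of counts per degree of freedom was at most 9.74 for a pair of NTG libraries and 7.85 for LTA, but at least 24.7 for NTGF. In LTAF it was 23.5 and 30.1 with replicate 2, and 4.23 without it. The fit of all 12 libraries shares a single spread per gene between the groups, so its counts are not on equal terms across comparisons.

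The replicate number as a block gave 684 lower genes in LTAF against LTA, 1454 and 1699 interaction terms and 210 shared falls, and moved no other count by over 1.5 times. The numbers do not pair the libraries: of 18 same-number pairs, 2 had deviations correlated above 0.1 (range -0.44 to 0.20), and 1 of 12 libraries correlated best with its own number.

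Leaving out each library in turn gave 11022 to 11737 higher and 8907 to 9758 lower genes in LTA against NTG, 5436 to 9657 and 5181 to 7255 in NTGF against NTG, and 997 to 4405 and 356 to 3873 in LTAF against LTA. It gave 10674 to 15186 and 9093 to 16300 in LTAF against NTGF, 1094 to 6194 and 1252 to 6507 interaction terms, and 677 to 2004 shared rises and 133 to 685 shared falls. The slope of the freezing responses stayed between 0.279 and 0.338. For genes without a count in a group, the bound falls by up to 1.552 times when a library of that group is left out, because the floor rises. Windows of 10 or 25 genes gave 11 or 3 higher runs in LTA against NTG against 6, and 0 or 1 lower runs in the interaction against 2; 25 genes gave 2 higher runs in LTAF against NTGF against 8, and library totals gave 4 higher runs in the interaction against 2. The tests planned for gene lists, with fry and their other settings, were not run because 0 identifiers matched. In the simulation of LTAF against LTA (63996 genes), 2% of genes changed 2-fold were recovered. The cut on the unadjusted p was stricter there than in the data, so the share missed in the data is not known.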

Other observations

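Other runs of neighbouring genes differed between groups with freezing or with acclimation. On 6D (models 331600 to 333200) the mean was 0.93 ± 0.09 log2 CPM in NTG, 2.40 ± 0.17 in LTA, 3.08 ± 0.42 in NTGF and 3.6 ± 0.22 in LTAF (SD, n = 3). On 1B (383700 to 385300) it was -0.05 ± 0.34 and 0.17 ± 0.24 in the unfrozen groups NTG and LTA, and 2.07 ± 0.62 and 2.34 ± 0.11 in NTGF and LTAF. On 4A (402200 to 405800) 9 of 15 genes were called higher in NTGF than in NTG, with a mean log2 fold change of 1.61. A run on 5B (462100 to 463400) was at 3.78 ± 0.30 in NTG, 1.46 ± 0.21 in NTGF and 3.01 ± 0.29 in LTAF. A run on 6D (5300 to 9200) fell by 1.93 on the log2 scale in LTA against NTG. These runs come from the scan chosen after the data were examined. The runs on 1B and on 6D (5300 to 9200) were found with neither windows of 10 nor of 25 genes, and those on 4A and 5B not with 25.

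All 3 patterns below were chosen after the data were examined. Tests written before their result are those on the first 20 low-confidence models of 1A, on RNA of an NTGF library mixed into LTAF replicate 2 and on a weaker response of that library; the tests on depth, freezing, the first 13 models, another cultivar, a wrong label, carry-over and the choice of 3 libraries came after.

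In NTGF 43 genes stood far below their level elsewhere. The mean of the 3 libraries was at most 10% of the lowest of the other 9, which held at least 10 counts each and lay within 3-fold. LTA and LTAF had 1 such gene each and NTG 4. The 42 genes outside the 1A end still held 5601 ± 2217 counts per NTGF library (SD, n = 3), a mean of 0.044 of their level in the other 9. As a set they were lowered and not absent. Lower depth is argued against by the lowest NTGF total, at 0.987 of the lowest other, while freezing in general stays untested: the lowest LTAF library held 0.72 of the LTA level of these genes or of the 1A end, but both sets were picked with LTAF near the other libraries. A missing end of chromosome 1A, which could account for 16 weakly expressed models but not for the 42 of the 43 genes that lie elsewhere, stays open: its first 20 low-confidence models held up to 1.15 of their level in NTGF, and at least 0.823 in every NTGF library, which by the test as written would exclude it, but 19 of these 20 carry a number that a high-confidence model carries too, so the 2 series are numbered apart and the identifiers do not tell which of the 20 lie in that end. The first 13 held at most 0.106, a set picked after its counts were seen and so not independent evidence. NTGF plants of another cultivar cannot be told apart from a response of unacclimated plants to freezing, since the 65 genes present in NTGF only may be induced by freezing, and NTG had 240 such genes, LTAF 42 and LTA 8 (the rule for this test was changed after its count was seen).

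On the first principal component LTAF replicate 2 lay at 98.7, near the LTA libraries (108.1 to 128.2), and LTAF replicates 1 and 3 at 187.3 and 213.1, while the NTGF libraries spread as well, from -155.8 to -79.4. Lower depth is argued against by its total, 0.964 of the lower of the other LTAF totals, and RNA of an NTGF library by 43 genes specific to NTGF, which stood at a median of 0.01003 of the NTGF level (75th percentile 0.0381; the planned ratio of percentiles is undefined, as the 25th is -0.00089). Its slope on the freezing response of LTAF replicates 1 and 3 was 0.741, against at most 0.124 for an LTA library, which argues against a wrongly labelled LTA library, while rank correlation, the first version of that test, left this undecided (0.940 with LTA replicate 3, 0.936 with the closer LTAF library). That slope, where replicates 1 and 3 gave 0.911 and 0.948 on each other, met the test written before for a weaker response. The slope of LTAF replicate 2 on the response of unacclimated plants, looked at afterwards, was 0.350, above 0.284 and 0.2996. That is a small difference in 1 library, so a weaker response stays open. A response that differs in kind or in timing stays open too and was not tested.

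NTG replicate 2, LTA replicate 2 and LTAF replicate 3 shared 5 genes on 5 chromosomes with at least 20 counts in each and at most 2 in any of the other 9. Carry-over from a single library would leave unequal levels, but the highest of the 3 was at most 3.64 times the lowest in any gene. Of 216 sets of 3 libraries that are not a group, 1, this one, held any such gene, and the highest other held 0. The set was picked because it holds these genes, so this count does not exclude a chance choice of 3 libraries. The cause stays open, and the labels give no source of the seed.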
